A study of Hydra vulgaris with 12 samples.

How the data were processed

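RNA was measured in Hydra of strain 105, a freshwater cnidarian polyp that regrows its head after amputation. Per the labels, each sample pooled 50 to 100 animals that had been starved for 1 day and carried a young bud. The trunk between bud and head was divided by eye into regions. Animals were bisected at the border of the uppermost region, R1, and the next one, R2. After 0, 2, 4, 6, 12 or 48 h of regeneration the tissue of R2 and R3 was taken for RNA. Each time has 2 samples, which gives 12 libraries. Since a pool was collected for each sample, the p-values rest on the spread between pools handled in this study, pooled over all times. Whether the 2 pools of a time were collected on the same day is not given in the sources used here, so this spread may not cover differences between days.

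Total RNA had integrity numbers above 9.0 and went through 2 rounds of poly(A) selection, per the labels' protocols. Strand-specific libraries were made by marking the second cDNA strand with deoxyuridine, amplified for 13 to 15 PCR cycles and read as 50 bp single ends. The submitters' processing notes name Bowtie 0.12.8, a short-read aligner. The genome or transcript build, the way reads were assigned to transcripts and any filter are not given in the sources used here. The deposited table holds RPKM, read numbers scaled to transcript length and to the mapped reads of the library, computed by the authors for 17353 transcripts in each library. Of these, 16988 carry the RefSeq prefix of a predicted mRNA, 364 that of a predicted non-coding RNA and 1 that of a curated mRNA.

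The low values were examined for steps that would reveal whole reads, and none were found. Between 1489 and 1968 transcripts per library lay above 0 but below 0.001 RPKM, so fractions of reads appear to have been shared among similar transcripts. Sequencing depth is therefore unknown, no counting interval or detection limit is given, and values of closely related transcripts are uncertain. RPKM totals differed between libraries, from 1330540 to 1535760, and further scaling between libraries is not given in the sources used here.

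RPKM values were analysed as log2(RPKM + 1), so a fold change on this scale understates that of weakly expressed transcripts. Transcripts with at least 1 RPKM in at least 2 of the 12 libraries were tested, which left 14283. One linear model with a mean per time was fitted to all 12 libraries in limma 3.58.1 under R 4.3.3, with a prior variance that follows mean expression (6 residual degrees of freedom). Changes from 0 h were tested at the 5 later times, along with the 4 steps from 2 to 4 h, 4 to 6 h, 6 to 12 h and 12 to 48 h. A transcript was said to rise or fall when limma's Benjamini-Hochberg adjusted p was below 0.05 and the log2 fold change was at least 1 in size. A moderated F-test over the 5 contrasts with 0 h, adjusted in the same way, served for change at any time. Standard errors (SE) are those of limma, all tests were two-sided, and values of groups are means ± SD of 2 libraries. Where a transcript lies near 0 RPKM at several times, its replicates agree there almost by construction on this scale. Its SE and p-value then partly reflect that floor and can understate the spread at times when it is expressed. XM_004206511.1 and XM_004212923.1, named below, were near 0 RPKM in most libraries.

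Names were sought in the table and in a list of RefSeq genes of a Hydra assembly other than the authors' source, used for names alone. The table paired 1 identifier with a name, Wnt3, and 1 identifier matched the list. For that reason 18 gene lists written in advance, for signalling pathways, cell types and cell functions, could not be tested: 1 list, Wnt signalling, had a member, against a minimum of 5. Under the naming rule set in advance for this case, the text names Wnt3 and, for each comparison with 0 h, the 2 transcripts with the largest rise and the 2 with the largest fall among those past the threshold. In the steps between neighbouring times, transcripts already named in this way are followed. Transcripts named outside the rule are said to be so.

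The procedure was tested on simulated data for 48 h against 0 h over 14283 transcripts. Each transcript was given normal noise with the spread of the real fit, the same at all 6 times. The procedure recovered 60 of 100 transcripts changed by 1.5 on the log2 scale and 93 of 100 changed by 3, and called 6 of 14083 unchanged transcripts. In the data the SD of the log2 difference between replicates was 1.015 at 48 h and 0.732 at 0 h, against 0.425 at 4 h. The simulation therefore does not show the share of false calls where the spread differs between times, as in this comparison.

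The groups, tests, naming rule and alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 RPKM, quantile normalization, scaling of each library by its median ratio to the geometric mean over libraries, no variance trend, limma's weights per library, a term for the replicate number, fits of only the 4 libraries compared, no minimum fold change, and leaving out each library in turn. When a library is left out, its time keeps a single library that is assumed to vary like the other times. Fits of only the 4 libraries compared were read for counts alone, so the ranges given for single transcripts do not include them. A fit with 0 h and 48 h reduced to their first libraries, and a filter at a mean of 10 RPKM, were added after seeing the data. Comparisons that share the 0 h libraries share their chance deviations, so overlaps among them were not computed.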

Results

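Transcript levels were measured by strand-specific poly(A) RNA sequencing in the regenerating upper trunk of Hydra at 6 times after bisection, with 2 pools of animals at each time. Each of the 12 libraries gave an RPKM value for 17353 transcripts. Between 14492 and 16866 transcripts had a value above 0, with the fewest in 48 h replicate 2 and the most in 2 h replicate 1. Replicates correlated across transcripts with r of 0.948 at 0 h, 0.975 at 2 h, 0.982 at 4 h, 0.980 at 6 h, 0.946 at 12 h and 0.910 at 48 h. 0 h replicate 1 correlated better with a 2 h library (0.964) than with its partner, and 48 h replicate 1 and both 12 h replicates did so with a 4 h library (0.922, 0.952 and 0.949). The median RPKM of a library was highest in 0 h replicate 1, at 14.5, and lowest in 48 h replicate 2, at 9.56. The 20 most abundant transcripts of a library held 13.5% and 13.8% of all RPKM in the 0 h replicates, 22.6% and 22.0% at 12 h, and 17.1% and 17.5% at 48 h.

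The comparisons with 0 h ask how the tissue differed from tissue taken at bisection. No uncut animals kept for the same hours are among the samples. Effects of bisection therefore cannot be told apart from those of the time kept, such as possible longer starvation or time of collection. Relative to 0 h, the median transcript lay at −0.11 on the log2 scale at 2 h, −0.28 at 4 h, −0.30 at 6 h, −0.32 at 12 h and −0.39 at 48 h. After median-ratio scaling these medians were 0.022, −0.012, −0.014, −0.025 and −0.049. The balance of rises and falls therefore depends on the scaling, and both are given for each comparison.

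Wnt3, a secreted Wnt ligand of the Hydra head organizer, was the only transcript with a gene name. It averaged 2.35 ± 0.522 RPKM at 0 h, 4.04 ± 0.367 at 2 h, 6.10 ± 1.15 at 4 h, 7.22 ± 1.52 at 6 h, 7.82 ± 1.58 at 12 h and 11.2 ± 1.61 at 48 h (SD, n = 2). The ratios of these means to that at 0 h were 1.72, 2.59, 3.07, 3.33 and 4.78. At every later time both libraries lay above both 0 h libraries. At 2 h the log2 fold change was 0.60 (SE 0.27) and did not pass the test, with a limma adjusted p of 0.325. Wnt3 rose by 1.08 at 4 h (adjusted p = 0.0219), by 1.29 at 6 h (0.00967), by 1.39 at 12 h (0.00579) and by 1.87 at 48 h (0.00141), each with an SE of 0.27. With median-ratio scaling, which removes the shift of the median transcript, the log2 fold changes were 0.68, 1.30, 1.52, 1.64 and 2.16. Wnt3 was the only member of the preset Wnt list that could be named, so adjusting over the list would change nothing. Its unadjusted limma p was 0.0546 at 2 h, 0.00303 at 4 h, 9.8e-04 at 6 h, 5.84e-04 at 12 h and 6.63e-05 at 48 h. The 4 h call was lost without 0 h replicate 1 (adjusted p = 0.0932), 0 h replicate 2 (0.0561), 4 h replicate 1 (0.143) or 4 h replicate 2 (0.0725), within a range of 0.0103 to 0.143 over 22 alternatives. The 6 h call was lost without 6 h replicate 1 (0.0748, range 0.00451 to 0.0748), and the adjusted p at 12 h and 48 h stayed below 0.05 in all 22 alternatives. With a pseudocount of 5 the log2 fold changes at 4, 6 and 12 h were 0.59, 0.73 and 0.80, under the minimum of 1. The 22 alternatives do not include the fits of only the 4 libraries compared, so whether Wnt3 passed in those is not given. There the total number of calls was 1696 in place of 2635 at 12 h and 523 in place of 3198 at 48 h.

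**Figure D1:**
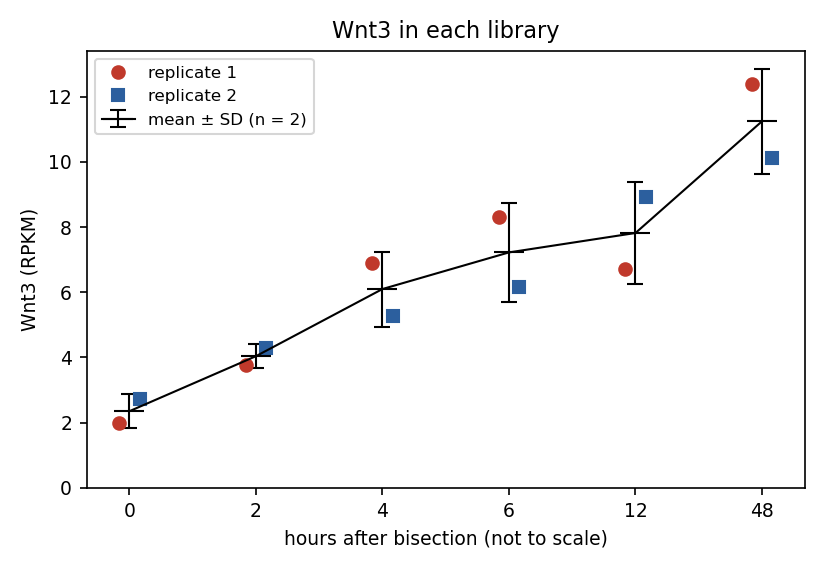
Wnt3 in RPKM (vertical axis) at each time after bisection in hours (horizontal axis, not to scale); points are single libraries and bars are the mean ± SD of 2 libraries. The mean goes from 2.35 RPKM at 0 h to 11.2 RPKM at 48 h.

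At 2 h, 19 transcripts rose and 16 fell. The largest rise was that of XM_002167331.2, which was below 0.001 RPKM in both 0 h libraries and at 45.7 ± 2.40 RPKM at 2 h (SD, n = 2; log2 fold change 5.54, SE 0.65, adjusted p = 0.0237). XM_004213329.1 stood at 0.0481 RPKM and below 0.001 RPKM in the 0 h libraries and at 40.1 and 20.3 RPKM at 2 h (log2 fold change 4.85, SE 0.34, adjusted p = 0.00124), and it held 73.1 RPKM or more in every library from 4 h on. The largest fall was that of XM_002167556.2, from 154 ± 22.1 to 9.67 ± 5.38 RPKM (log2 fold change −3.95, SE 0.36, adjusted p = 0.00678), and it stood at 129 ± 47.0 RPKM at 4 h. XM_004212923.1 fell from 8.60 ± 3.14 RPKM to below 0.001 RPKM in both 2 h libraries (log2 fold change −3.22, SE 0.35, adjusted p = 0.0173). It is listed at 0 in all 4 libraries of 12 h and 48 h. Median-ratio scaling gave 17 rises and 5 falls. The total of 35 was 2 without 0 h replicate 2, 5 without 2 h replicate 1, 6 h replicate 1 or 6 h replicate 2, 9 without 4 h replicate 1 or 4 h replicate 2, 19 without 2 h replicate 2, 12 h replicate 1 or 12 h replicate 2, 136 without 0 h replicate 1, 141 without 48 h replicate 1 and 139 without 48 h replicate 2. It was 145 with weights per library, and limma fitted to only the 4 libraries compared gave 0, with 2747 transcripts at an unadjusted p below 0.05. The calls of all 4 transcripts named above were thus lost in that fit, which the ranges below do not include. XM_002167331.2, XM_002167556.2 and XM_004212923.1 lost their calls without 0 h replicate 2, at adjusted p of 0.213, 0.0943 and 0.191, and XM_002167331.2 and XM_004212923.1 also without 2 h replicate 1 (0.131 and 0.101), 2 h replicate 2 (0.0805 and 0.0634), 6 h replicate 1 (0.0570 for both) or 6 h replicate 2 (0.0567 for both). A pseudocount of 0.1 also ended the calls of XM_002167331.2 (0.0654) and XM_004212923.1 (0.0632), a filter at 5 RPKM that of XM_004212923.1 (0.0599), and 0 h and 48 h reduced to their first libraries, an alternative chosen after seeing the data, those of all 3 transcripts (0.139, 0.0854 and 0.0933 in the order above), within ranges over alternatives of 8.22e-04 to 0.213, 0.00251 to 0.0943 and 0.00107 to 0.191.

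At 4 h, 650 transcripts rose and 1059 fell. XM_004210825.1 was below 0.001 RPKM in all 4 libraries of 0 h and 2 h and reached 530 ± 37.0 RPKM at 4 h (SD, n = 2; log2 fold change 9.05, SE 0.35, adjusted p = 5.29e-06). The predicted non-coding transcript XR_181873.1 went from below 0.001 RPKM in the same 4 libraries to 196 ± 0.982 RPKM (log2 fold change 7.62, SE 0.41, adjusted p = 3.96e-05). XM_004206511.1 fell from 310 ± 14.4 RPKM at 0 h, through 58.1 ± 8.22 at 2 h, to below 0.001 RPKM in both 4 h libraries (log2 fold change −8.28, SE 0.23, adjusted p = 6.39e-07). XM_004212948.1 fell from 138 ± 2.23 RPKM to 0.00249 RPKM and below 0.001 RPKM in the 4 h libraries (log2 fold change −7.12, SE 0.57, adjusted p = 1.97e-04). Median-ratio scaling gave 956 rises and 377 falls, moving the share of rises from 38.0% to 71.7%, and quantile normalization gave 833 and 545. The total of 1709 was 944 without 0 h replicate 2, 1003 without 4 h replicate 1 and 840 without 4 h replicate 2.

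At 6 h, 762 transcripts rose and 1274 fell. XM_004210825.1 stood at 557 ± 250 RPKM (SD, n = 2; log2 fold change 9.05, SE 0.35, adjusted p = 3.54e-06). XM_004213212.1, below 0.001 RPKM in both 0 h libraries, was at 758 and 217 RPKM (log2 fold change 8.67, SE 2.27, adjusted p = 0.0234). The largest fall was that of XM_004208578.1, from 1536 ± 11.9 RPKM to 1.08 and 1.32 RPKM in the 6 h libraries (log2 fold change −9.45, SE 0.25, adjusted p = 3.19e-07). XM_004206511.1 remained below 0.001 RPKM in both libraries (log2 fold change −8.28, SE 0.23, adjusted p = 3.19e-07). Median-ratio scaling gave 1086 rises and 465 falls, moving the share of rises from 37.4% to 70.0%, and quantile normalization gave 997 and 676. The total of 2036 was 1198 without 0 h replicate 2 and 1018 without 6 h replicate 2. XM_004213212.1 lost its call without 0 h replicate 1 (adjusted p = 0.0801), 0 h replicate 2 (0.10), 6 h replicate 1 (0.116), 6 h replicate 2 (0.0822) or the filter (0.0575), within a range of 0.00809 to 0.116 over 23 alternatives.

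At 12 h, 787 transcripts rose and 1848 fell. XM_004210825.1 reached 2062 and 1103 RPKM (log2 fold change 10.56, SE 0.35, adjusted p = 1.77e-06), and XR_181873.1 stood at 386 and 151 RPKM (log2 fold change 7.92, SE 0.41, adjusted p = 1.7e-05). XM_004210848.1 fell from 378 ± 1.25 RPKM at 0 h to below 0.001 RPKM in both 12 h libraries (SD, n = 2; log2 fold change −8.57, SE 1.26, adjusted p = 0.00187). XM_004206511.1 was again below 0.001 RPKM in both (log2 fold change −8.28, SE 0.23, adjusted p = 6.39e-07). Median-ratio scaling gave 1241 rises and 819 falls, moving the share of rises from 29.9% to 60.2%, and quantile normalization gave 1112 and 992. The total of 2635 was 1725 without 0 h replicate 2 and 1696 in a fit of only the 4 libraries compared.

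At 48 h, 755 transcripts rose and 2443 fell. XM_004210825.1 stood at 552 ± 152 RPKM (SD, n = 2; log2 fold change 9.08, SE 0.35, adjusted p = 4.63e-06). XM_004208918.1 rose from 0.149 and 0.431 RPKM to 405 and 234 RPKM (log2 fold change 7.91, SE 1.66, adjusted p = 0.00696). XM_004206511.1 stood below 0.001 RPKM in 48 h replicate 1 and at 0.00913 RPKM in replicate 2 (log2 fold change −8.27, SE 0.23, adjusted p = 6.43e-07), and XM_004212948.1 below 0.001 RPKM in both (log2 fold change −7.12, SE 0.57, adjusted p = 2.2e-04). Median-ratio scaling gave 1295 rises and 1216 falls, moving the share of rises from 23.6% to 51.6%, and quantile normalization gave 1232 and 1192. The total of 3198 was 1880 with weights per library and 523 in a fit of only the 4 libraries compared. XM_004208918.1 lost its call with weights per library (adjusted p = 0.106) and with 0 h and 48 h reduced to their first libraries (0.0598), an alternative chosen after seeing the data, within a range of 0.0038 to 0.106 over 23 alternatives.

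**Figure D2:**
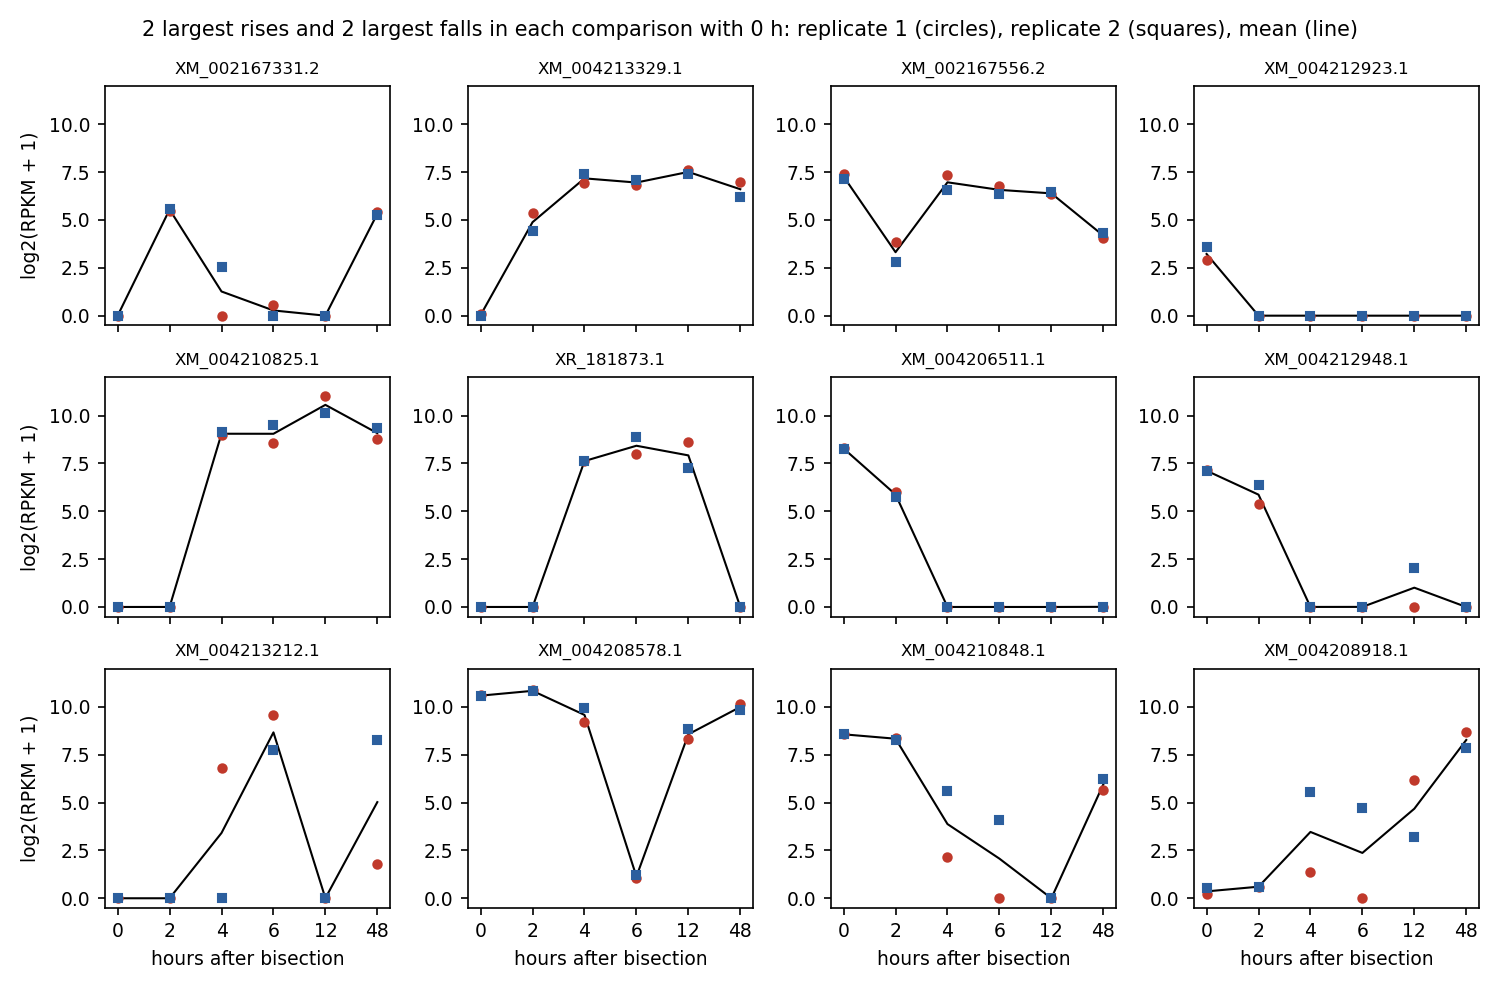
Levels of the 12 transcripts that were among the 2 largest rises or the 2 largest falls in any comparison with 0 h, as log2(RPKM + 1) (vertical axes) against hours after bisection (horizontal axes, not to scale); circles and squares are replicates 1 and 2 and the line joins their means. XM_004206511.1 goes from 310 RPKM at 0 h to below 0.001 RPKM at 4 h, and XM_004208578.1 is low at 6 h, at 1.08 and 1.32 RPKM, and at 1027 RPKM at 48 h.

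The steps between neighbouring times ask when the changes took place. From 2 to 4 h, 475 transcripts rose and 345 fell. Of the 13 transcripts named here, 4 rose and 4 fell at this step. XM_004210825.1 rose by 9.05 on the log2 scale (SE 0.35, adjusted p = 7.04e-06) and XR_181873.1 by 7.62 (SE 0.41, adjusted p = 7.92e-05). XM_004206511.1 changed by −5.88 (SE 0.23, adjusted p = 7.04e-06) and XM_004212948.1 by −5.87 (SE 0.57, adjusted p = 7.54e-04). XM_004213329.1 and XM_002167556.2 also rose and XM_002167331.2 also fell. XM_004208578.1 fell by 1.26 on the log2 scale (adjusted p = 0.0156) and lost its call without 2 h replicate 1 (0.0915), 2 h replicate 2 (0.0697) or 4 h replicate 1 (0.110), within a range of 0.00249 to 0.110 over 23 alternatives. The log2 fold change of Wnt3 was 0.49 (SE 0.27) and did not pass, with an adjusted p of 0.299. Median-ratio scaling gave 622 rises and 205 falls, moving the share of rises from 57.9% to 75.2%. The total of 820 was 349 without 2 h replicate 1, 518 without 2 h replicate 2, 283 without 4 h replicate 1, 353 without 4 h replicate 2 and 1292 with weights per library.

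From 4 to 6 h, 19 transcripts rose and 11 fell. XM_004208578.1 fell from 787 ± 269 RPKM to 1.08 and 1.32 RPKM (SD, n = 2; log2 fold change −8.44, SE 0.25, adjusted p = 1.04e-06), and the other 12 transcripts named here did not pass. The log2 fold change of Wnt3 was 0.21 (SE 0.27, adjusted p = 1). The total of 30 was 6 without 4 h replicate 1, 8 without 4 h replicate 2, 14 without 6 h replicate 1, 4 without 6 h replicate 2, 18 without 0 h replicate 1 or 0 h replicate 2, and 47 without 48 h replicate 1 or 48 h replicate 2. It was 143 with weights per library and 2 in a fit of only the 4 libraries compared.

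From 6 to 12 h, 141 transcripts rose and 206 fell. XM_004208578.1 rose from 1.08 and 1.32 RPKM to 385 ± 97.6 RPKM (SD, n = 2; log2 fold change 7.43, SE 0.25, adjusted p = 3.27e-06), and the other 12 transcripts named here did not pass. The log2 fold change of Wnt3 was 0.10 (SE 0.27, adjusted p = 0.897), and it was −0.0877 without 6 h replicate 2 and −0.0817 without 12 h replicate 2. The total of 347 was 60 without 6 h replicate 1, 52 without 6 h replicate 2, 181 without 12 h replicate 2, 191 without 4 h replicate 1, 192 without 4 h replicate 2, 531 without 48 h replicate 1 and 527 without 48 h replicate 2. In a fit of only the 4 libraries compared it was 1.

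From 12 to 48 h, 350 transcripts rose and 667 fell. Of the 13 transcripts named here, 3 rose and 3 fell at this step. XR_181873.1 fell from 268 ± 166 RPKM to below 0.001 RPKM in both 48 h libraries (SD, n = 2; log2 fold change −7.92, SE 0.41, adjusted p = 8.49e-05). XM_002167556.2 fell from 82.9 ± 3.99 to 17.2 ± 2.04 RPKM (log2 fold change −2.21, SE 0.36, adjusted p = 0.00668). XM_002167331.2, below 0.001 RPKM in both 12 h libraries, rose to 39.1 ± 3.11 RPKM (log2 fold change 5.32, SE 0.65, adjusted p = 0.00196); its 2 h level was 45.7 ± 2.40 RPKM. XM_004208578.1 rose from 385 ± 97.6 to 1027 ± 175 RPKM (log2 fold change 1.43, SE 0.25, adjusted p = 0.00903). XM_004210848.1 rose by 5.95 on the log2 scale (SE 1.26, adjusted p = 0.0200) and XM_004210825.1 changed by −1.48 (SE 0.35, adjusted p = 0.0323), but both lost their calls in several alternatives. The log2 fold change of Wnt3 was 0.48 (SE 0.27, adjusted p = 0.296). The total of 1017 was 636 without 12 h replicate 2, 2340 without 48 h replicate 1 and 229 with weights per library, and limma fitted to only the 4 libraries compared gave 0, with 1958 transcripts at an unadjusted p below 0.05. With weights per library XM_002167556.2, XM_002167331.2 and XM_004208578.1 lost their calls, at adjusted p of 0.166, 0.0964 and 0.158, the highest over their 23 alternatives. These alternatives do not include the fit of only the 4 libraries compared, where no transcript passed. Every call named at this step was therefore lost in that fit. XM_004210825.1 passed in 14 of 23 alternatives (adjusted p from 0.0251 to 0.275) and not without 2 h replicate 1 (0.0515), 2 h replicate 2 (0.0514), 4 h replicate 1 (0.0565), 4 h replicate 2 (0.0564), 12 h replicate 1 (0.141) or 48 h replicate 1 (0.0779), without the filter (0.0689), with weights per library (0.275) or with 0 h and 48 h reduced to their first libraries (0.0582). XM_004210848.1 passed in 17 of 23 (0.00843 to 0.337) and not without 12 h replicate 1 (0.0746), 12 h replicate 2 (0.0837) or 48 h replicate 2 (0.0713), without the filter (0.0562), with weights per library (0.337) or with 0 h and 48 h reduced to their first libraries (0.0933).

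**Figure D3:**
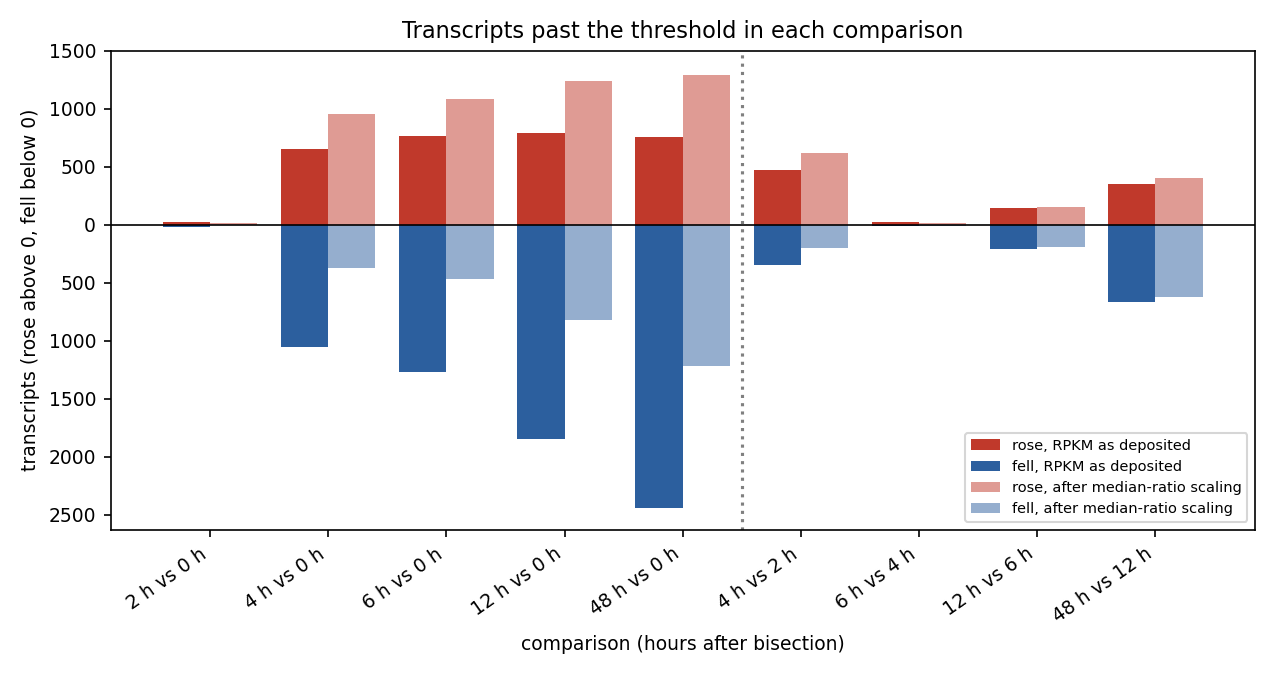
Number of transcripts that rose (above 0) and fell (below 0) in each comparison (horizontal axis), from RPKM as deposited (dark) and after median-ratio scaling (light); the dotted line parts comparisons with 0 h from steps. At 48 h against 0 h, 755 rose and 2443 fell as deposited, against 1295 and 1216 after scaling.

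Over all times, 5876 of the 14283 transcripts passed the F-test, or 41.1%, Wnt3 among them (adjusted p = 0.00647). Of these, 42.3% had their highest mean at 0 h, 13.7% at 2 h, 7.13% at 4 h, 12.7% at 6 h, 8.99% at 12 h and 15.2% at 48 h. The lowest mean was at 48 h in 37.9% and at 0 h in 13.0%. The 2 replicates taken singly placed the highest value at the same time in 69.0% of these transcripts. They placed the lowest value at the same time in 56.8%, so the times of single transcripts are uncertain. Among the 4917 transcripts that passed after median-ratio scaling, the highest mean was at 0 h in 20.5% and at 48 h in 25.9%, and the lowest at 0 h in 29.3% and at 48 h in 26.7%.

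**Figure D4:**
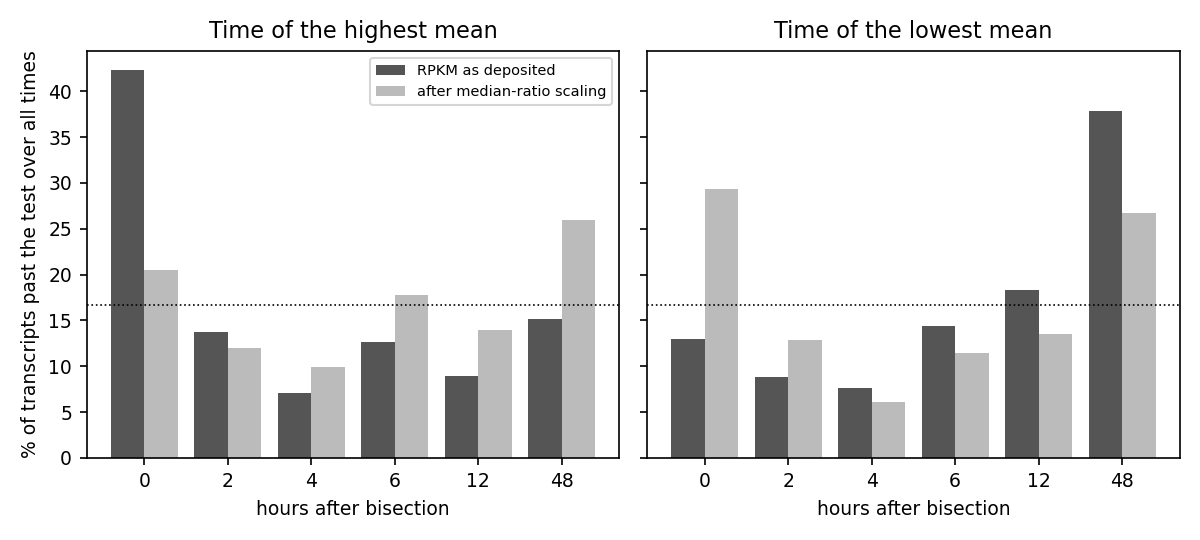
Share of the transcripts past the F-test (vertical axes, percent) with their highest mean (left) or lowest mean (right) at each time in hours (horizontal axes), from RPKM as deposited (dark) and after median-ratio scaling (light); the dotted line marks an even share of 16.7%. The share with the highest mean at 0 h is 42.3% as deposited and 20.5% after scaling.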

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

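The fits with 0 h and 48 h reduced to their first libraries and with a mean of at least 10 RPKM were chosen after seeing the data. Of 248 counts under alternatives, 181 stayed within 1.5 times the reported count and 67 moved further. The total for 2 h against 0 h, reported as 35, was 22 with a pseudocount of 0.1, 78 with a pseudocount of 5, 55 with quantile normalization, 22 with median-ratio scaling, 12 with no trend, 145 with weights per library, 4 with 0 h and 48 h reduced to their first libraries and 95 with a mean of at least 10 RPKM. Without a minimum fold change the totals were 3137 at 4 h, 3588 at 6 h, 4404 at 12 h and 5045 at 48 h against 0 h, 1465 from 2 to 4 h and 534 from 6 to 12 h, by construction higher. With weights per library they were 1880 at 48 h against 0 h, 1292 from 2 to 4 h, 143 from 4 to 6 h and 229 from 12 to 48 h. With no trend the step from 4 to 6 h gave 16, and with 0 h and 48 h reduced to their first libraries the step from 6 to 12 h gave 589. For these settings other than the minimum fold change, the cause was not tested. Fits of only the 4 libraries compared, with 2 residual degrees of freedom in place of 6, gave 0 at 2 h, 1696 at 12 h and 523 at 48 h against 0 h, and 2 from 4 to 6 h, 1 from 6 to 12 h and 0 from 12 to 48 h. Where limma gave 0, 2747 transcripts at 2 h and 1958 from 12 to 48 h had an unadjusted p below 0.05. The same fits gave 1775 at 4 h and 2044 at 6 h against 0 h and 1147 from 2 to 4 h, where 1709, 2036 and 820 were reported. The SD of the log2 difference between replicates was 0.481 at 2 h, 0.425 at 4 h and 0.455 at 6 h. It was 0.732 at 0 h, 0.756 at 12 h and 1.015 at 48 h. A spread shared by all times understates that of the most variable ones, so counts involving 48 h in particular may be too high. Leaving out 1 library at a time gave 2 to 141 at 2 h, 840 to 2024 at 4 h, 1018 to 2343 at 6 h, 1725 to 2985 at 12 h and 2345 to 3990 at 48 h against 0 h, 283 to 1043 from 2 to 4 h, 4 to 47 from 4 to 6 h, 52 to 531 from 6 to 12 h, 636 to 2340 from 12 to 48 h and 4240 to 7806 over all times. The log2 fold change of Wnt3 from 6 to 12 h, not past the test, reversed to −0.0877 without 6 h replicate 2 and −0.0817 without 12 h replicate 2, and ranged up to 0.291 over the left-out libraries. No other named result changed direction. The depth of the libraries is unknown, so its effect on weakly expressed transcripts could not be measured. The tests of the 18 gene lists and their alternatives, an estimated correlation among them, were not run because at most 1 member of a list could be named.

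The replicate numbers do not pair samples in the labels. Deviations of same-numbered libraries correlated across transcripts between −0.0976 and 0.234 over the 15 pairs of times, with 1 pair above 0.1. A replicate block gave 13 transcripts at 2 h against 0 h and 13 from 4 to 6 h, stayed within 1.5 times the reported count elsewhere and changed no named call.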

Other observations

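The overlap below, the 4 tests of replicate spread at 0 h and 48 h and the 5 tests of libraries that correlate best with another time were chosen after the results were seen, and bootstrap intervals were added to the tests of the 20 most abundant transcripts after their values were seen. The bootstrap intervals below draw transcripts, not libraries, so they do not cover the spread between pools. Many transcripts that rose by 4 h fell again between 12 and 48 h. The 4 h against 0 h and 48 h against 12 h comparisons share no library. Of the 650 transcripts that rose in the former, 214, or 32.9%, fell in the latter, where 30.4 would be shared by independent lists (Fisher's exact odds ratio 14.3, 95% interval 11.8 to 17.3). In the opposite direction, 101 of the 1059 that fell by 4 h rose from 12 to 48 h, against 26.0 for independent lists (odds ratio 5.49, 4.27 to 7.02). After median-ratio scaling the shared numbers were 230 against 41.7 and 63 against 10.6. In the same direction, as deposited, 8 rose in both comparisons, against 15.9 for independent lists, and 32 fell in both, against 49.45. Transcripts are not independent replicates, so the intervals understate the uncertainty. Both lists also come from the same fit, with a variance per transcript shared over all 12 libraries, so the lists are not independent. In a fit of only its 4 libraries the 48 h against 12 h list held 0 transcripts.

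XM_002168126.2, the transcript with the highest mean over the 12 libraries, followed such a course and was chosen after its values were seen. At 0, 2 and 48 h it stood below XR_181676.1, which was at 21878, 21339 and 15394 RPKM. XM_002168126.2 stood at 3722 ± 310 RPKM at 0 h, 5126 ± 2494 at 2 h, 49938 ± 381 at 4 h, 54696 ± 6471 at 6 h, 43355 ± 1993 at 12 h and 6800 ± 2440 at 48 h (SD, n = 2). The log2 fold change was 3.75 at 4 h against 0 h (SE 0.34, limma adjusted p = 3.49e-04) and −2.72 at 48 h against 12 h (SE 0.34, adjusted p = 0.00211), and at 48 h against 0 h it was 0.82 and did not pass (adjusted p = 0.0884).

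Wnt3 was among 66 transcripts whose mean rose at every step from 0 to 48 h, and 410 fell at every step. Of the 360 distinct orders of the 6 times, only the true order, 1 of 360, gave as many as these 476 transcripts, with 468 in the next and a median of 21. After median-ratio scaling the true order gave 152 upward and 210 downward, 362 in all, against 340 in the next. The true order thus ranked first, as a progressive change along the time course would give, but by a small margin. Any course in which neighbouring times resemble each other can also favour this order. As deposited, the median transcript also lay lower at each later time, which can add to the falls. Progressive change in these transcripts therefore remains a hypothesis.

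In RPKM as deposited the typical transcript was lower after bisection, and from 4 h on falls outnumbered rises against 0 h. After median-ratio scaling, which removes this shift, rises outnumbered falls at those times. At 2 h, with a median of −0.11, 19 rose and 16 fell as deposited. A candidate explanation of the lower typical transcript is the larger share of the 20 most abundant transcripts. Leaving these out and rescaling each library moved the mean of the median log2 fold changes at 4, 6 and 12 h from −0.30 to −0.19 (95% bootstrap interval −0.20 to −0.18), and the median at 48 h from −0.39 to −0.34 (−0.35 to −0.32). The tests argue against these transcripts as the whole source of either shift. By mean level, the transcripts ranked 1 to 20 held 11.5% ± 0.153 of all RPKM at 0 h, 18.6% ± 0.232 at 4 h, 17.0% ± 0.296 at 6 h, 21.1% ± 0.421 at 12 h and 15.35% ± 0.11 at 48 h (SD, n = 2). Those ranked 21 to 500 held 45.9% ± 0.24 of all RPKM at 0 h, 45.55% ± 0.674 at 4 h, 46.6% ± 0.481 at 6 h, 43.0% ± 0.255 at 12 h and 46.9% ± 0.524 at 48 h. Those ranked 501 to 2000 held 20.4% ± 0.185 at 0 h and 18.95% ± 0.274, 19.4% ± 0.177, 18.9% ± 0.187 and 19.6% ± 0.11 at these later times, and those ranked 2001 and below 22.1% ± 0.208 at 0 h and 16.9% ± 0.168, 17.0% ± 0.6, 17.1% ± 0.352 and 18.2% ± 0.744. The authors' scaling stays open and was not tested. RPKM is scaled to the mapped reads of each library, so a change in RNA per cell shared by all transcripts would cancel out.

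Replicates differed most at 48 h, and 0 h replicate 2 also stood apart, with 1834 transcripts listed at 0 against 503 in replicate 1. Among 1909 transcripts with a mean of at least 100 RPKM, the median absolute log2 difference between replicates was 0.283 for the 48 h pair. It was 0.204 at 2 h, 0.1645 at 4 h and 0.138 at 6 h. The 48 h value was 1.72 times the median of the 2, 4 and 6 h pairs (95% bootstrap interval 1.6 to 1.84, 2.31 over all transcripts). This leans against shallower sequencing of 48 h replicate 2 as the whole cause. With 1 pair per time, and reference pairs this unequal, it does not settle the question. At 0 h that ratio was 0.987 (0.921 to 1.07, 1.38 over all transcripts), as shallower sequencing of 0 h replicate 2 could give. Among the same 1909 transcripts the SD of the log2 difference was 0.554 at 0 h. It was 0.557 at 2 h, 0.379 at 4 h and 0.377 at 6 h. By this measure the 0 h pair was wider than the 4 h and 6 h pairs, so the question is not settled at 0 h either. The second replicates correlated better with their partners than with any library of another time, by 0.0285 at 48 h (95% bootstrap interval over transcripts 0.0235 to 0.0333) and 0.0177 at 0 h (0.0151 to 0.0203), which argues against another time for these 2 libraries. The first replicates did not: 48 h replicate 1 correlated best with a 4 h library (0.922, against 0.910 with its partner) and 0 h replicate 1 with a 2 h library (0.964 against 0.948), and both 12 h replicates did so with a 4 h library (0.952 and 0.949 against 0.946). Among abundant transcripts that separated the other replicate of its time from both libraries of that other time by at least 1 on the log2 scale, 48 h replicate 1 lay closer to its partner than to 4 h in 81.1% of 433 (95% bootstrap interval 77.1% to 84.8%), and 12 h replicates 1 and 2 in 78.4% of 111 (70.3% to 85.6%) and 79.3% of 121 (71.9% to 86.0%), where true 4 h libraries put in their place did so in at most 10.5%, which argues against 4 h for these 3 libraries. For 0 h replicate 1 the share closer to its partner than to 2 h was 59.0% of 78 (48.7% to 69.2%), against 21.8% and 39.1% for the 2 h libraries, which left 2 h undecided. A test over all 1909 transcripts with a mean of at least 100 RPKM was added after that outcome. The median absolute log2 difference of 0 h replicate 1 was 0.162 to its partner and 0.293 to either 2 h library. This gap of −0.13 (95% bootstrap interval −0.14 to −0.11) argues against 2 h for this library. Differences between pools of animals in the course of regeneration stay open and were not tested.

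Of 5039 transcripts past the threshold in any comparison with 0 h, 51, or 1.01%, switched between below 0.01 RPKM at one time and 10 RPKM or more at another, XM_004210825.1 and XM_004206511.1 among them. Of the 213 values below 0.01 RPKM in the 51 transcripts, 159 were above 0. XR_181873.1, XM_002167331.2, XM_004212948.1, XM_004213212.1 and XM_004210848.1 also had both libraries of one time below 0.01 RPKM. At another time both of their libraries were above 10 RPKM. Most transcripts named for the largest rises and falls thus show such gaps, and the limit below applies to them. Such gaps also lay between the 2 replicates of one time: 155 transcripts at 0 h, 24 at 2 h, 15 at 4 h, 29 at 6 h, 144 at 12 h and 370 at 48 h were below 0.1 RPKM in one replicate and above 5 RPKM in the other, with replicate 2 the low one in 139 at 0 h and 305 at 48 h. Reads moved between similar transcripts could produce such switches. A transcript with the opposite course was found for 12 of the 51 and for 6 of 51 controls matched on level, a ratio of 2 with a 95% bootstrap interval of 0.9 to 6.5, so reads moved between rows of similar transcripts and a true switch cannot be told apart with so few. Of 330 predicted non-coding transcripts 49.7% passed the F-test, against 40.9% of mRNAs (Fisher's exact odds ratio 1.43, p = 0.00151), but mRNAs matched on level passed in 54.2% of 1650 (odds ratio 0.836, 95% interval 0.655 to 1.07, Fisher's exact p = 0.147), which argues against the RefSeq class of the transcript as the source of a higher share.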
